A study of Mus musculus with 2 samples.

How the data were processed

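The series holds chromatin immunoprecipitation sequencing (ChIP-seq) of H3K27ac, an acetylation of histone H3 found at active promoters and enhancers, in hindbrain tissue of B6NCrl mouse embryos of embryonic day 11.5. Both samples belong to 1 group, and the labels number them as biological replicates 1 and 2. Replicate 1 was made from the tissue of 109 embryos of mixed sex and replicate 2 from that of 88. The labels give both replicates the same donor, while the numbers of embryos differ, and they were taken here as separate pools of embryos. How far their spread is biological is not given in the sources used here. It is the only measure of error between samples, and no comparison between conditions was possible. Intervals over regions or genes, and motif standard errors over chromosomes, describe 1 peak list and not the variation between embryos.

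The deposited files are 4 peak lists on the mouse build mm10. The authors called peaks on each replicate alone and on both replicates pooled, and derived a list of replicated peaks from the pooled list and the 2 replicate lists, per the text files deposited with the samples. The peak caller, its threshold, the control's depth and the rule behind the replicated list are not given in the sources used here. Each peak carries the authors' fold enrichment over the control, which is a ratio and ran from 1.29 to 72.9 over the lists. Each deposited peak also has a −log10 p and a −log10 q, and the lowest −log10 p was 2.01. A q of at most 0.05 was held by 81.0% of replicate 1, 90.0% of replicate 2, 84.4% of pooled and 98.4% of replicated peaks. The display score that the authors deposited with each peak was not used. The summit position in bp from the peak start, another of the authors' values, was used only to centre the sequence windows. Fold enrichment describes a peak within its own list, and it was used here only to describe or rank peaks and, as a description, to correlate the replicate lists.

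The numbers of peaks were 69246 in replicate 1, 50981 in replicate 2, 59680 in the pooled list and 34137 in the replicated list. They covered 33.3, 25.0, 34.3 and 27.8 Mb. No peaks overlapped within a list. The files give no read counts, so the sequencing depth is unknown and no counting interval could be set on a peak. All computations used peaks on chromosomes 1 to 19, X and Y, which left out 8, 6, 7 and 5 peaks on unplaced scaffolds. Peaks of the replicated list had the coordinates and values of pooled peaks. Of its 34132 peaks on chromosomes, 6062 (17.8%) lacked an overlap in at least 1 of the replicate lists, and 141 lacked it in both.

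Genes came from GENCODE M21, whose coordinates are those of the same build, and sequence from the matching GRCm38 reference. A gene was called marked when a peak overlapped by 1 bp or more a window of 1 kb on each side of any of its protein-coding transcript starts. Marked genes were counted over 21829 protein-coding genes. The choices of gene lists, tests and settings described here were made before the data were examined, except where stated. The 23 gene lists held 317 genes, and En1 stood in both the rhombomere list and the midbrain list. Each list was compared with all other protein-coding genes by a two-sided Fisher's exact test, adjusted by Benjamini-Hochberg over the 23 lists with a threshold of 0.05. Genes are not replicates, so these tests compare gene groups within 1 peak set, and the 2 replicate lists give the spread.

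Region shares were set beside 100 random placements of the same intervals on the same chromosomes outside assembly gaps. For distal acetylation, the bases in replicated peaks within 100 kb of a gene's start and more than 1 kb from any protein-coding start were counted. The median of each list was placed as a percentile among 10000 random lists of the same size, matched on 5 classes of gene density, and percentiles under 2.5 or over 97.5 were counted as outside. Domains were made by joining peaks with gaps of up to 12.5 kb and ranked by the bases inside peaks. Consensus words for 15 factor families were searched on both strands in 500 bp around the summits of distal peaks and in control windows 10 kb away outside every peak list. Odds ratios were combined over 10 classes of GC content by the Mantel-Haenszel method, with a standard error from leaving out each chromosome in turn and adjustment over the 15 families.

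Genes were named by a fixed rule. For each list it takes the 3 members with the strongest promoter peak by the authors' fold enrichment in the replicated list, or 4 for the Hox, rhombomere, neuron subtype, forebrain and midbrain lists. It also takes every unmarked member of a list with at most 4 unmarked members and every marked member of a list with at most 4 marked ones. To these it adds the 10 genes with the strongest promoter peak, the nearest protein-coding start of the 10 largest domains and the 5 strongest distal peaks. Other genes are said to have been chosen after their values were seen.

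The alternatives tried were promoter windows of 500 and 2500 bp, the gene's own 5′ end, a −log10 q of at least 5, the pooled list and each replicate list alone in place of the replicated list. A background of the same CpG class, stricter overlap rules, a distal window of 50 kb, unmatched random lists, a stitching gap of 5 kb and a sequence window of 200 bp were also tried. The high CpG class had an observed to expected CpG ratio of at least 0.6 in 1 kb around the gene's start. The use of only those peaks that were overlapped in both replicate lists, and a motif search without repeat-masked bases, were chosen after seeing the data.

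The computations for gene lists, replicate overlap, fold correlation, distal windows, motifs and domains were tested on simulated data. The random placements as a reference, the regional comparisons, the CpG classes, the test of promoters marked in 1 replicate alone and the microRNA permutations were not. For the gene lists, 88.5% of lists with planted marks and 2.5% of unchanged lists were called, over 21829 genes. Nearly all members of the planted lists were marked, so the 88.5% does not hold for lists closer to the background. For the overlap, a planted 58.72% was recovered as 58.74% over 5000 regions, and for the correlation of fold a planted 0.7 as 0.709. For the distal windows, all planted lists and 6% of random lists fell outside the limits. For the motifs, a planted odds ratio of 2.08 was recovered as 2.07 in 8000 windows. Those windows were random sequence without a difference in GC content or repeats, so the GC allowance and the masking were not tested. The work used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and samtools 1.23.1.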

Results

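H3K27ac was mapped in the hindbrain of mouse embryos at embryonic day 11.5, when the segments of the hindbrain (rhombomeres) have formed and neurons are being born. There was 1 group of 2 biological replicates, pools of 109 and 88 embryos. The lists of peaks gave 69246 regions for replicate 1 and 50981 for replicate 2, and the authors' replicated list gave 34137. The depth of sequencing is unknown. The question addressed was which genes and regions carry the mark in this tissue, and fold values below are the authors' fold enrichment in the replicated list unless a replicate list is named.

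The strongest promoter regions stood in both replicate lists. The region at Setd1b, which encodes a histone methyltransferase, had a fold enrichment of 61.7 in replicate 1 and 62.4 in replicate 2. At Nr2f1, a transcription factor of the nuclear receptor family, the values were 54.1 and 49.8, and at Zc3h4 they were 61.5 and 55.4. Promoters of 10015 genes were marked in both replicate lists, 1355 in replicate 1 alone and 529 in replicate 2 alone. Of the replicate 1 regions, 45.7% were overlapped by replicate 2 (95% Wilson interval 45.3 to 46.0), against a mean of 2.11% for random placements. For replicate 2 regions the share was 66.3% (65.9 to 66.7), against 2.85%. Across the 27895 merged regions found in both lists, which are not independent replicates, the fold values had a Spearman rho of 0.768 and 98.1% differed by less than 2 times. In the strongest 10% of each list by fold, 99.96% and 100% of the peaks were overlapped, and in the weakest 10% the shares were 19.2% and 40.1%. With a −log10 q of at least 5 in both lists the shares were 70.9% and 84.5%, and when 50% of both regions had to be shared they were 28.8% and 39.2%.

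**Figure D1:**
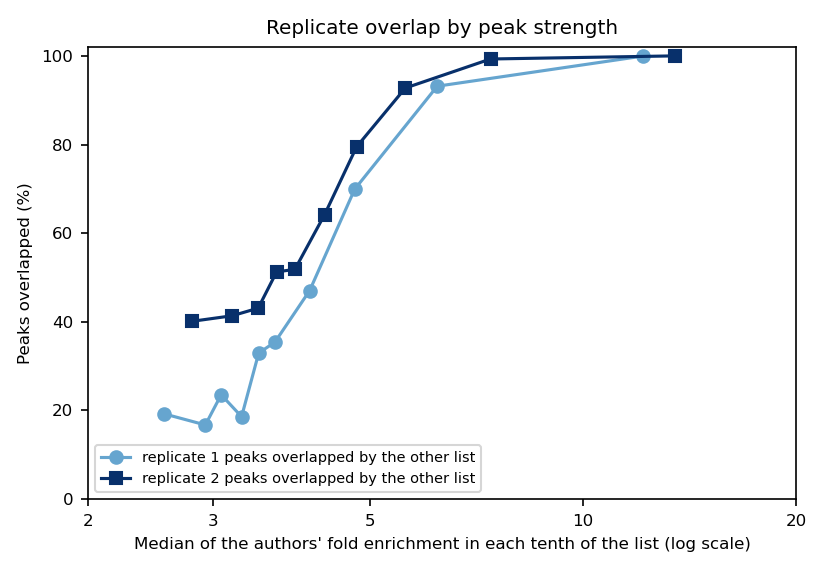
Share of peaks overlapped by the other replicate list (vertical axis, percent) in 10 equal parts of each list ordered by the authors' fold enrichment, plotted at the part's median fold (horizontal axis, log scale). The share was 19.2% in the weakest and 99.96% in the strongest part of replicate 1, and 40.1% and 100% for replicate 2.

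Promoters held 12508 (36.6%) of the 34132 replicated regions on chromosomes, 10.1 times the mean of 3.64% for random placements. The 10 genes with the strongest promoter regions were Setd1b (fold 72.89), Zc3h4 (67.1), Nr2f1 (65.0), Kmt5b (64.4), Erbin (59.0), Cyth2 (58.9), Tnrc18 (57.9), Klf7 (57.1), Kansl1 (56.9) and Brd2 (56.7). Setd1b and Kmt5b encode histone methyltransferases, Kansl1 a subunit of a histone acetyltransferase complex and Brd2 a reader of acetylated histones. The Setd1b region lay at chromosome 5, 123135649 to 123143740, and covered the 5′ end of the gene. Introns held 30.2% of the regions, exons outside promoters 5.92% and intergenic sequence 27.2%, against 32.0%, 7.41% and 57.0% for random placements. Chromosome X had 3.28 regions per Mb and 0.592 per protein-coding gene. Autosomes had 9.47 to 24.4 per Mb and 1.13 to 2.28 per gene. The promoter share was 24.4% and 29.8% in the lists of replicates 1 and 2, 26.9% in the pooled list and 47.1% at a −log10 q of at least 5.

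The Hox genes, which specify position along the body axis, were marked at the anterior end of their clusters. Of the 12 genes of paralogue groups 1 to 4, 10 carried a promoter region, with the highest fold at Hoxa2 (40.0), Hoxb2 (27.8), and Hoxb3 and Hoxb4 (25.3, a single region over both promoters). Hoxb1 and Hoxd1 had no promoter region in either replicate list. None of the 16 genes of groups 9 to 13 was marked in the replicated list, although Hoxd10 had a region in replicate 1 and Hoxb9 in replicate 2. The difference between these 2 lists was 83.3 percentage points (Fisher's exact test, adjusted p = 5e-06) and lay between 58.3 and 83.3 points in the 8 alternatives run. Hox genes lie side by side in 4 clusters and neighbours can share a region, so they are not independent. The exact p values given for the Hox lists here and below do not allow for this. Of the 11 genes of groups 5 to 8, 7 were marked (adjusted exact p = 0.445 against other genes). The highest fold values in this list were 12.8 for Hoxc5, 10.2 for Hoxb5, 8.27 for Hoxa5 and 7.75 for Hoxb8, and Hoxc6, Hoxa7, Hoxc8 and Hoxd8 were unmarked. Hoxa7 had a region in replicate 1 alone (4.11) and Hoxc6 in replicate 2 alone (3.48).

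In the replicated list the last marked gene along each cluster was Hoxa6 in HoxA, Hoxb8 in HoxB, Hoxc5 in HoxC and Hoxd4 in HoxD. These ends moved with the setting: Hoxa6 was lost at a −log10 q of at least 5, Hoxa7 and Hoxb9 were gained in the pooled list, Hoxa7 and Hoxd10 without replicate 2, and Hoxc6 and Hoxb9 without replicate 1. With each gene's own 5′ end Hoxc4 was the last in HoxC and no HoxD gene was marked. The annotated 5′ ends of Hoxd3 (74711927) and Hoxd4 (74711929) on chromosome 2 lie outside their strongest regions, which start at 74729979 and 74727209. That of Hoxa3 (52213336 on chromosome 6) lies beyond Hoxa6, so its annotated body also holds Hoxa4, Hoxa5 and Hoxa6. Marks lost in this setting depend on the annotated start and do not show that other starts lack acetylation. The Hoxa2 region ran from 52162521 to 52172755 on chromosome 6, over most of the gene and the sequence upstream of it. The shared Hoxb3 and Hoxb4 region ran from 96316911 to 96347452 on chromosome 11. Regions covered 98.4% of the Hoxb3 gene body (97.49% and 97.93% in the lists of replicates 1 and 2), 100% of Hoxb4 and 67.5% of Hoxa3, but 0% of Hoxb1 and Hoxd1. Groups 1 to 4 were marked more often than other genes (83.3% against 47.1%, adjusted exact p = 0.033), and groups 9 to 13 less often (adjusted exact p = 0.000249). The higher share of groups 1 to 4 did not pass with the background in the same CpG class (adjusted exact p = 0.0519), with the pooled list (0.0723), without replicate 2 (0.0716) or with each gene's own 5′ end (0.471), where Hoxa3, Hoxd3 and Hoxd4 lost their mark.

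**Figure D2:**
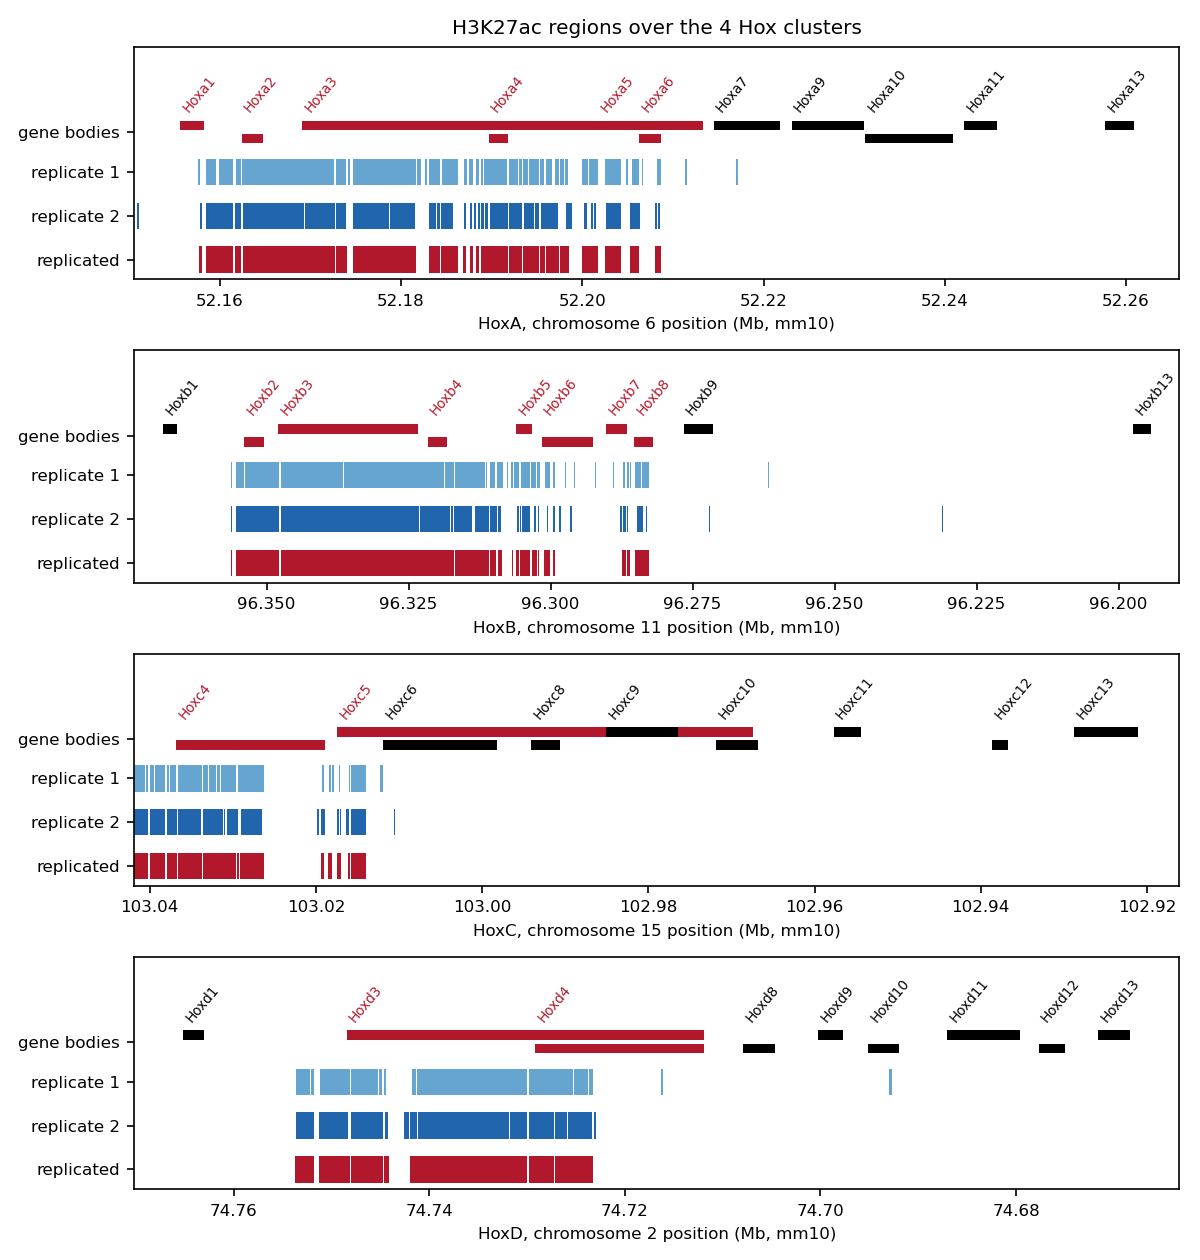
Maps of the 4 Hox clusters (horizontal axis, mm10 position in Mb), drawn with paralogue group 1 or the lowest group at the left, with annotated gene bodies and the peaks of replicate 1, replicate 2 and the replicated list. Gene names and bodies in red have a promoter region in the replicated list; no gene of groups 9 to 13 does, and the regions of that list end near Hoxa6, Hoxb8, Hoxc5 and Hoxd4, while single replicate lists have regions further on.

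Patterning and neuron subtype genes of the hindbrain, most of which encode transcription factors, were marked more often as a pooled set than the pooled forebrain and midbrain genes. With En1 left out as a member of both sides, 34 of 41 hindbrain genes (82.9%) and 3 of 28 forebrain and midbrain genes (10.7%) had a promoter region. The odds ratio was 37.2 (95% exact interval 8.32 to 246) with an adjusted p of 4.53e-09 by Fisher's exact test. The difference of 72.2 percentage points stayed between 63.6 and 73.3 points in the 8 alternatives run. It rested mainly on the neuron subtype factors (24 of 25 marked) and the forebrain factors (1 of 20). The rhombomere and midbrain lists did not pass against other genes, and hindbrain genes were not tested against midbrain genes alone. Among the 25 listed factors of hindbrain neuron subtypes, 24 were marked (96.0%, adjusted exact p = 7.19e-06). The list was not restricted to factors particular to the hindbrain. The contrast with forebrain and midbrain genes therefore does not separate hindbrain identity from neural identity in general. Their highest fold values were 16.7 at Neurog2, 16.5 at Ascl1 and 10.5 at Neurog1, proneural factors, and 9.85 at Pax3. Phox2a, a factor of cranial motor and noradrenergic neurons, was the unmarked member and had a region in replicate 1 alone. Atoh1 (4.72), a factor of rhombic lip neurons, and Mnx1 (2.88), a motor neuron factor, lacked a region in replicate 2; both were named after their values were seen.

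Of the 17 genes of rhombomere and isthmus patterning, 11 were marked (64.7%, adjusted exact p = 0.209). Irx3 had a fold of 38.1, Meis1 34.4, Meis2 32.3 and Pbx1 26.1, the last 3 encoding partners of Hox proteins. The 6 unmarked members, named after their values were seen, were Egr2, Pax5, Pax8, Fgf8, Wnt1 and Cyp26c1. Pax8 had a region in both replicate lists. Without replicate 1, 14 of the 17 were marked and the list passed (adjusted exact p = 0.0139), and it also passed with the pooled list (0.00699). Of the 20 forebrain factors only Dlx2 (fold 4.61) was marked, and the list was marked less often than other genes (adjusted exact p = 0.000284). The pooled list and the setting without replicate 2 each had 3 marked (Dlx1 and Gsx2 added), and windows of 500 bp had 0. Foxg1, Emx2, Six3 and Nkx2-1, named after their values were seen, had no promoter region in either replicate list. Of the 9 midbrain genes, En1 (9.43), Nr4a2 (7.89) and Th (2.70) were marked (adjusted exact p = 0.563). Otx2, a midbrain and forebrain factor named after its values were seen, was unmarked but had a region in both replicate lists (3.63 and 3.05). Th had no region in replicate 2, and with the pooled list or without replicate 2 the marked members numbered 5, above the background share.

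**Figure D3:**
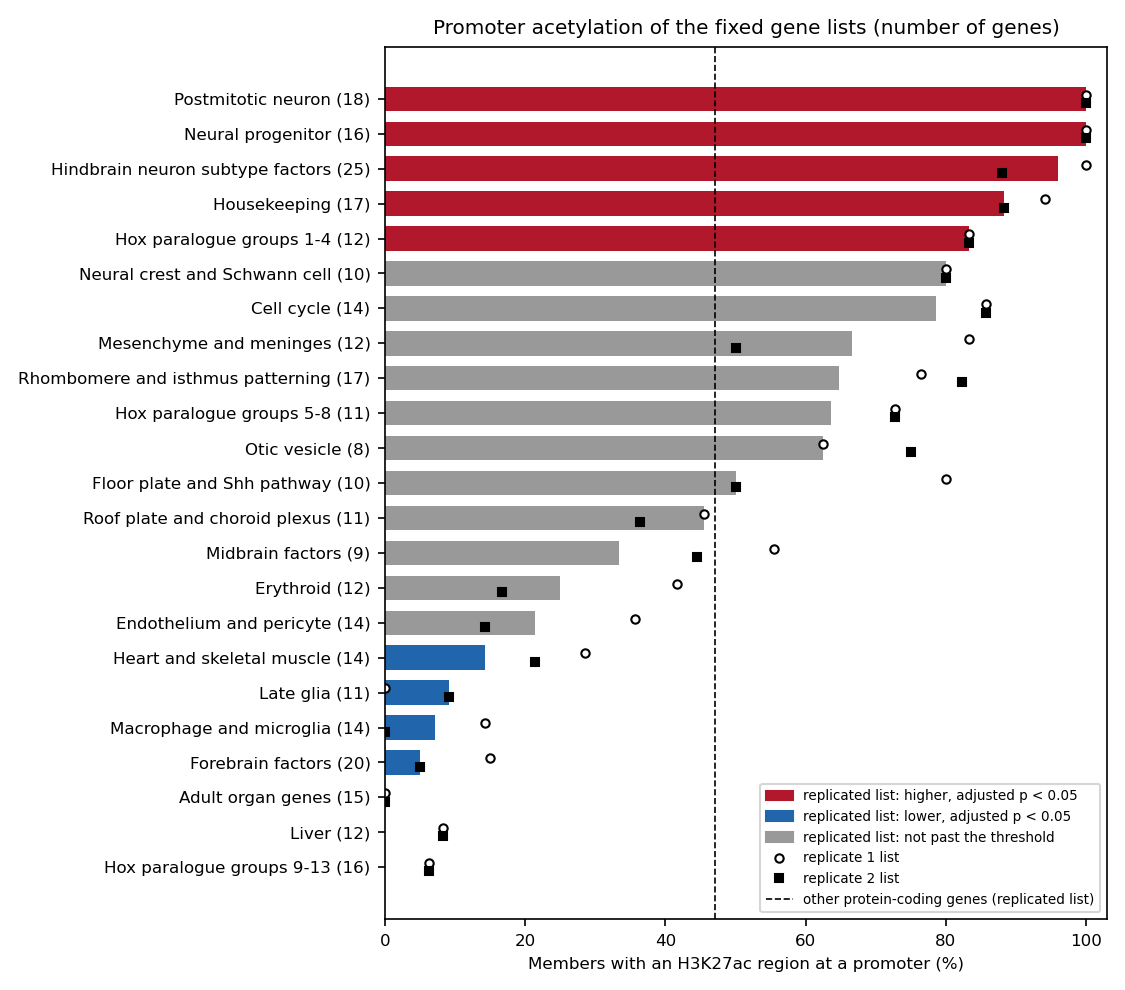
Percent of each list's genes (number in parentheses) with an H3K27ac region within 1 kb of a protein-coding transcript start in the replicated list (bars), in replicate 1 (open circles) and in replicate 2 (filled squares). The dashed line is the share of other protein-coding genes, 47.1%; red lists were higher and blue lists lower by Fisher's exact test at an adjusted p under 0.05, and the lists with no bar had no marked gene.

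The listed genes of neural progenitors and of neurons were all marked in the main setting. All 16 progenitor genes had a promoter region in the replicated list and in both replicate lists (adjusted exact p = 4.47e-05, Fisher's exact test). The highest fold values were 51.2 at Msi1, an RNA-binding protein of neural stem cells, 31.6 at Sox2 and 29.9 at Hes5, an effector of Notch signalling whose region also covered the Pank4 promoter. All 18 genes of postmitotic neurons were marked in each of the 3 lists (adjusted exact p = 1.48e-05), led by Nhlh2 (30.4), Myt1 (26.7), and Map2 and Rbfox3 (21.01 each). The Sox2 region lay at chromosome 3, 34650030 to 34652075, over the 5′ end of the gene. Both lists kept their calls under every alternative run. At the gene's own 5′ end 14 of the 16 progenitor genes were marked, and Pax6 and Notch1 were not.

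The floor plate and Shh pathway list and the roof plate and choroid plexus list were marked at shares near that of other genes. In the floor plate and Shh pathway list 5 of 10 genes were marked, with fold values of 31.5 at Ptch1, the Shh receptor, 13.9 at Ntn1 and 4.96 at Gli1. The list held 8 marked genes in replicate 1 and 5 in replicate 2 (adjusted exact p = 1 for the replicated list by Fisher's exact test). In the roof plate and choroid plexus list 5 of 11 were marked (adjusted exact p = 1), with the highest fold at Msx2 (6.28), Lmx1a (5.33) and Wnt3a (4.50), and 3 were marked at a −log10 q of at least 5. The choroid plexus genes Ttr, Folr1, Kcne2 and Aqp1, named after their values were seen, had no promoter region in either replicate list. Gdf7 and Bmp6 were also unmarked. Regions of the otic vesicle list, an organ that forms beside the hindbrain, stood at 5 of 8 genes (adjusted exact p = 0.561), led by Eya1 (21.3), Eya4 (6.78) and Six1 (6.28), while Oc90, Tbx1 and Fgf10 were unmarked.

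Markers of other cell types that hindbrain tissue could hold were also counted. Of the 10 genes of neural crest and Schwann cells 8 were marked (adjusted exact p = 0.0887), with Tfap2a at 22.9, Sox9 at 16.2 and Tfap2b at 9.43, and Plp1 and Snai2 unmarked. With a −log10 q of at least 5 the list passed at the same count (adjusted exact p = 0.042). At the gene's own 5′ end 6 of the 10 were marked, and Tfap2a and Ets1 lost their mark. Sox9 is also expressed in neural progenitors. Of the 12 genes of mesenchyme and meninges 8 were marked (adjusted exact p = 0.317), with Prrx1 at 9.48, Pdgfra at 6.78 and Foxc1 at 5.53, and Col1a2, Dcn, Lum and Tbx18 unmarked. This list had 10 marked genes in replicate 1 and 6 in replicate 2. In the endothelium and pericyte list Fli1 (6.78), Kdr (5.51) and Emcn (4.10) were marked of 14 (adjusted exact p = 0.0967, and 0.0241 without replicate 1, where 2 were marked). The pooled list marked 7 of these genes and the setting without replicate 2 marked 5. In the erythroid list Klf1 (4.13), Nfe2 (3.83) and Hba-x (3.16) were marked of 12 (adjusted exact p = 0.209), 5 without replicate 2 (Hbb-bh1 and Spta1 added), 2 without replicate 1, and none at a −log10 q of at least 5 (adjusted exact p = 0.00446). The macrophage and microglia list had 1 marked gene of 14, Cd68 (3.65), and was marked less often than other genes (adjusted exact p = 0.00574). Cd68 had no region in replicate 2, and the count was 0 without replicate 1, 2 without replicate 2 and 3 in the pooled list.

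Genes of later glia and of other organs were marked less often than other protein-coding genes. Mbp (4.58) was marked of 11 genes of late glia (adjusted exact p = 0.0303), Myh7 (4.67) and Nppa (4.58) of 14 genes of heart and skeletal muscle (adjusted exact p = 0.0313), and none of the 12 liver genes (adjusted exact p = 0.00196) or the 15 adult organ genes (adjusted exact p = 0.000319), all by Fisher's exact test. Of genes in the high CpG class 78.9% were marked and of those in the low class 20.1%, and the macrophage, glia, liver, muscle and adult organ lists held 1, 2, 0, 2 and 0 genes of the high class. Against a background of the same class none of these 5 lists passed, with adjusted p values of 0.291, 0.238, 0.2499, 0.449 and 0.135. Liver had 1 marked gene in each replicate list. Mbp had no region in replicate 1, and late glia did not pass with windows of 2500 bp (adjusted exact p = 0.110), the gene's own 5′ end (0.0564), a −log10 q of at least 5 (0.0520) or the pooled list (0.0611). Muscle did not pass under the last 3 of these (0.0564, 0.0777 and 0.162), without replicate 1 (3 of 14 marked, adjusted exact p = 0.0802) or without replicate 2 (4 of 14, 0.152), and macrophage not with the pooled list (0.0611). The forebrain list and Hox groups 9 to 13 passed under each of these alternatives, including the background of the same CpG class.

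Housekeeping genes were marked at 15 of 17 promoters (adjusted exact p = 0.00243, Fisher's exact test). Ywhaz had a fold of 39.6, Hmbs 24.6 and Eef1a1 24.4, and B2m and Gusb were unmarked. Of the 14 cell cycle genes 11 were marked, led by the replication helicase subunits Mcm7 (15.9, a region also over the Ap4m1 promoter), Mcm5 (10.2) and Mcm4 (9.86, also over the Prkdc promoter), and Pcna, Mcm3 and Bub1 were unmarked (adjusted exact p = 0.0505). Pcna had a region in both replicate lists, and with 12 of 14 marked the cell cycle list passed without replicate 1 (adjusted exact p = 0.0139) and without replicate 2 (0.0292).

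More than 1 kb from coding starts, genes of the neural progenitor, neuron and hindbrain lists had more acetylated sequence around them than random lists matched on gene density. Parts of broad promoter peaks beyond 1 kb were counted here, and the random lists were not matched on promoter marking. These values are therefore not independent of the promoter results. The median within 100 kb of the gene start was 8.69 kb for neural progenitor genes, 5.24 kb for postmitotic neuron genes and 4.21 kb for neuron subtype factors, each above all 10000 random lists, whose medians centred on 0.277, 0.276 and 0.235 kb. Rhombomere and isthmus genes had 3.83 kb, at the 99.99th percentile. Notch1 had 34.4 kb and Sox2 23.8 kb among progenitor genes, and Nhlh1 24.0 kb among neuron genes, values chosen after they were seen. The 3 Hox lists had medians of 30.6, 30.6 and 19.2 kb, including groups 9 to 13, whose genes share their windows with the acetylated ends of the clusters. Housekeeping genes had 2.23 kb (98.0th percentile), which was not outside without replicate 1 (84.3) or at a −log10 q of at least 5 (95.3). The other 15 lists lay within the limits, among them the forebrain list with 0.139 kb (41.3rd percentile) and the adult organ list with 0 kb.

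Among the 10 largest acetylated domains were the HoxA and HoxB clusters and the Mir9-1 and Mir9-3 loci. Stitching gave 16984 domains with a median of 0.985 kb of acetylated sequence, and 230 held 10 kb or more. With the stitching gap set in advance, the largest, on chromosome 11 from 88233350 to 88649491, held 134.7 kb in 127 regions. Its nearest protein-coding start was Ccdc182, and 92.3 kb of it lay in the body of Msi2, an RNA-binding protein related to Msi1. The next, on chromosome 8 from 120251357 to 120589791, held 130.9 kb, of which 130.2 kb lay in the body of Gse1, with the start of Gins2 nearest to its middle. The one after it, on chromosome 2 from 30629220 to 30808671, held 69.8 kb. It overlapped 9330198N18Rik and other non-coding genes, and its nearest protein-coding start was that of 1700001O22Rik. HoxB followed with 55.0 kb (nearest start Hoxb4) and the Mir9-3 locus on chromosome 7 with 46.7 kb, 29731 bp from the nearest start, that of Polg. The remaining 5 were at Zmiz1 (42.3 kb), HoxA (40.5 kb, nearest start 5730596B20Rik), Bahcc1 (39.0 kb), the Mir9-1 locus on chromosome 3 (38.4 kb, nearest start Rhbg) and Cxxc5 (37.9 kb). The order depended on the setting: with gaps of up to 5 kb HoxB was the largest (51.3 kb), ahead of domains in Gse1 (45.6 kb) and Msi2 (42.1 kb), and without replicate 1 the Gse1 domain (111.9 kb) was just above the Msi2 domain (111.8 kb). The Gse1 domain (125.0 kb) was also above the Msi2 domain (79.6 kb) with only those peaks overlapped in both replicate lists, a setting chosen after seeing the data. Without replicate 2 there were 26102 domains, whose largest 10 overlapped 6 of those named.

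The 5 strongest distal regions also had high fold values in both replicate lists. The strongest, at chromosome 5, 115489530 to 115490428, had a fold of 54.8 (46.6 and 46.4 in the replicate lists) and overlapped the small nuclear RNA genes Gm24265 and Gm24407, 4.81 kb from Sirt4. The next spanned 10316 bp of chromosome 13 from 83724157 to 83734472 (fold 52.8), overlapping the non-coding genes C130071C03Rik and Gm26803, 220 kb from Mef2c. Another, at chromosome 3, 17784614 to 17792262 (fold 50.9), overlapped Mir124-2hg, the host gene of a microRNA of neurons. The others overlapped 1810026B05Rik near Chd2 on chromosome 7 (fold 50.4), and Zmiz1os1 and Gm26660 near Zmiz1 on chromosome 14 (fold 47.3). All 5 were intergenic with respect to protein-coding genes.

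After allowing for GC content, consensus words of SOX, POU and HOX-PBX factors were more frequent in distal regions than in control windows. Among 20563 windows of 500 bp, the SOX words ACAATGG or ACAAAGG occurred in 24.7% against 17.6% of control windows, with an odds ratio of 1.63 (95% interval 1.53 to 1.74) after allowing for GC content. The POU word ATGCAAAT had an odds ratio of 1.71 (1.52 to 1.92), the HOX-PBX word 1.52 (1.37 to 1.68), the homeobox word TAATTA 1.41 (1.33 to 1.49) and the proneural E-box 1.27 (1.20 to 1.34). The HOX-PBX word occurred in 5.60% of distal and 5.42% of control windows, so its odds ratio rested mainly on the allowance for GC content. The homeobox word was less frequent in distal regions than in controls before that allowance (11.1% against 12.9%), as were the GATA (20.1% against 24.3%) and MEF2 words (0.856% against 0.924%). ETS (1.86), MEF2 (1.40), RFX (1.16) and GATA (1.12) words also passed with odds ratios above 1. MEF2 and HNF4 words had been included in advance for comparison, as those of factors of other tissues. The MEF2 value was close to that of the homeobox word, so a pass does not show that a word is particular to this tissue. NFI, TEAD, TCF/LEF, HNF4 and nuclear receptor words did not pass, with adjusted p values from 0.0581 to 0.902. The CTCF word, bound by a factor of chromatin loop anchors, had an odds ratio of 0.303 (0.245 to 0.376).

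Without bases masked as repeats in the reference the CTCF odds ratio was 0.977 (0.756 to 1.26). Masking removed 26.5% of the bases of control windows and 11.7% of those of distal windows. GC content was counted over the whole window, with masked bases as neither G nor C, so masking also changed the GC classes. The direction of its effect on the odds ratios was not tested. The masked search gave 1.42 for SOX, 1.52 for POU, 1.39 for HOX-PBX, 1.27 for homeobox and 1.21 for E-box words. For RFX, ETS and MEF2 words it gave 1.34, 1.99 and 1.22. None of these values is separated from the effect of the uneven masking. GATA (0.934) and TEAD words (0.948) had odds ratios below 1 that passed, opposite to their values with all bases, and TCF/LEF (0.916) and nuclear receptor words (0.289) also passed below 1. RFX also did not pass without replicate 2 (1.05) or in windows of 200 bp (0.969). ETS rested on 47 windows and did not pass without replicate 2 (1.30), in windows of 200 bp (2.13) or at a −log10 q of at least 5 (1.59). TEAD passed without replicate 1 (1.06) and without replicate 2 (1.08).

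**Figure D4:**
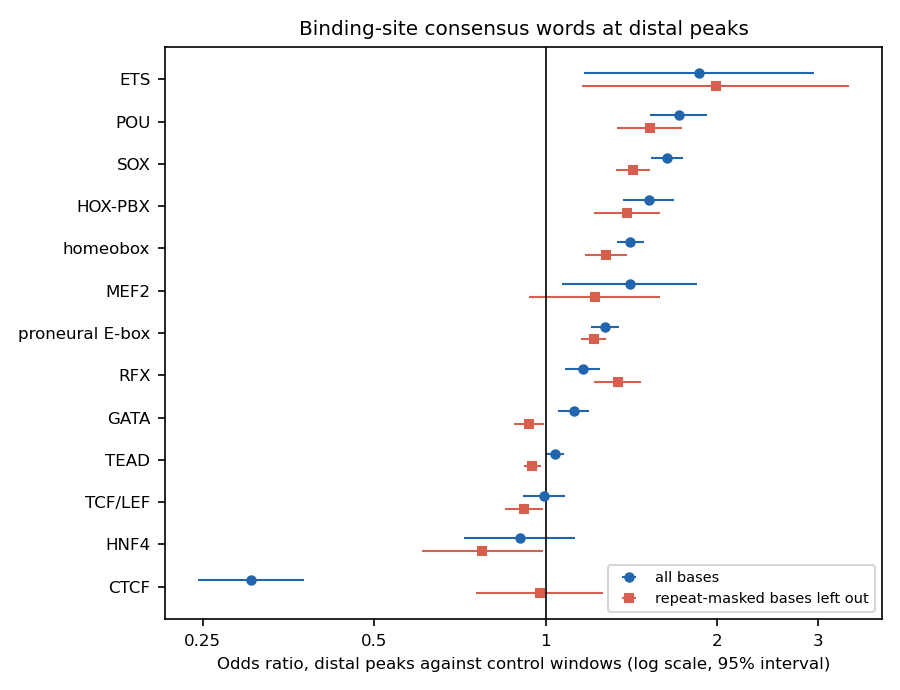
Odds ratio (horizontal axis, log scale, with 95% interval) of a consensus word in 500 bp around distal region summits against control windows, with all bases (blue circles) and with repeat-masked bases left out (red squares). The CTCF value moved from 0.303 to 0.977; NFI and nuclear receptor words, found in 8 and 6 distal windows, are not drawn.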

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

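The tests of cell mixtures and of weak peaks in replicate 1 were chosen only after the values they use had been seen, and the search for CTCF words without repeat-masked bases in windows beside the summit was also added after the other CTCF values. With 1 group in the design, no biological explanation was tested by comparing groups, and the tests of cell mixtures concern only the makeup of the dissected tissue.

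The comparisons left out 5 replicated peaks on unplaced scaffolds, with a median fold of 6.96 and a highest fold of 36.7. They were listed because their number was above the 3 that a count of 0 allows, which shows only that the authors called peaks there and tests no signal beyond those calls. A further 480 pooled peaks were overlapped by peaks of both replicate lists and were not in the authors' replicated list, with a median fold of 3.13.

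The CTCF word was less frequent in distal acetylated windows than in control windows (odds ratio 0.303). Repeats in the control windows are consistent with this: of 521 CTCF words in control windows 82.1% lay on repeat-masked bases, against 20.2% of 193 in distal windows, and the odds ratio without masked bases was 0.977. Masked bases made up 26.5% of the control windows and 11.7% of the distal windows, so the masked search covered less control sequence. Masking also changed the GC classes, so the odds ratio expected at equal densities is not known, and a smaller deficit is not excluded. An alternative, that CTCF sites lie beside the acetylated summit, stays open. Windows centred 750 bp away gave 0.783 (0.683 to 0.897) and 0.757 on the 2 sides with all bases, and 1.20 (0.935 to 1.53) and 1.28 (1.01 to 1.63) without masked bases.

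Promoters of mesenchyme and neural crest genes were marked in a dissection of the hindbrain, 16 of 22 members of the 2 lists. Neither list passed against other genes in the main setting (adjusted exact p = 0.317 and 0.0887, Fisher's exact test). Calls at the lower limit of the peak lists were excluded as the cause for most of the set, since 15 of the 16 stayed marked at a −log10 q of at least 5. The regions were still weak beside others, with a median fold of 5.43 against 8.66 for all marked genes. Foxc2 and Col1a1 lost their mark with only those peaks overlapped in both replicate lists. A promoter of a protein-coding neighbour under the strongest region was also excluded as the cause for the set. It was found for 1 of the 16, Mpz, whose region covers the Sdhc promoter. Promoters of non-coding neighbours were not checked and stay open. Cells of mesenchyme or crest in the dissected tissue stay open: of the 5 structural genes Col1a1, Col1a2, Col3a1, Dcn and Lum, 2 had a promoter region (3 in replicate 1 and 1 in replicate 2). Col1a1, 1 of these 2, had a fold of 2.25, a −log10 q of only 0.695 and no region in replicate 2. The median fold of the 16 was 5.43, beside 5.92 for the marked neuron subtype factors, and neural cells also express some of these genes, such as Sox9, so these values do not decide.

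Replicate 1 had 37612 merged regions with no counterpart in the other list and replicate 2 had 17148. The unshared peaks of replicate 1 lay mostly below a −log10 q of 5. Of all 69238 replicate 1 peaks on chromosomes, 45.7% were overlapped by the full replicate 2 list. Of the 18262 with a −log10 q of at least 5, 92.3% were overlapped by it. By fold, 99.96% of the strongest 10% of replicate 1 peaks were overlapped and 19.2% of the weakest 10%. Whether weak peaks at a permissive threshold explain the larger number in replicate 1 stays open. The 92.3% lay between the 95% that this explanation needed and the 80% that would have excluded it. A different mix of cell types in the 2 dissections cannot be told apart from this with the gene lists used. No list departed from the genome-wide ratio of 1355 to 529 promoters marked in 1 replicate alone (smallest adjusted p = 0.965, exact binomial test), but no list had more than 5 such genes.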

How the results depend on the processing

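The alternatives that used only replicated peaks overlapped in both replicate lists, and those that left repeat-masked bases out of the motif search, were chosen after seeing the data; all others were fixed before. Of 506 values under alternatives, 416 kept their direction and side of the threshold or moved by less than the spread, 30 lost a call, 21 gained one, 21 changed direction and 18 values without a test moved. The calls of Hox groups 9 to 13, neuron subtype factors, neural progenitor, postmitotic neuron, forebrain and housekeeping promoters held under all 9 alternatives run for them. Both regional comparisons held under the 8 run for them (58.3 to 83.3 and 63.6 to 73.3 percentage points), and they were not run within CpG classes. Each setting without a replicate used the authors' peak list of the other one alone, so it also changed the number of peaks. Depth is unknown, so absence of a peak is not absence of the mark. No paired analysis was possible because there was one group. The cause was not tested for the changes below, except where stated.

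For the replicate overlap, an overlap over 50% of the region gave 36.3% and 58.1% for replicates 1 and 2, 50% of both regions 28.8% and 39.2%, a −log10 q of at least 5 in both lists 70.9% and 84.5%, and the same number of peaks from each list 55.8% and 61.4%. The fold correlation was 0.820 at that q. The promoter share was 40.7% with windows of 2500 bp, which are wider by construction, 47.1% at a −log10 q of at least 5, 26.9% for the pooled list, and 24.4% to 29.8% without replicate 1 or 2.

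For promoters of gene lists, values are percent marked. With windows of 500 bp the floor plate list turned below the background (40%) and the cell cycle list passed (78.6%). With 2500 bp late glia did not pass (18.2%). With the gene's own 5′ end Hox groups 1 to 4 (58.3%), late glia (9.09%) and heart and skeletal muscle (14.3%) did not pass, the roof plate list turned above the background (45.5%), and the cell cycle list passed (78.6%). At a −log10 q of at least 5 the floor plate list turned below (40%), neural crest (80%) and erythroid (0%) lists passed, and late glia (9.09%) and muscle (14.3%) did not. With the pooled list Hox groups 1 to 4 (83.3%), macrophage (21.4%), late glia (18.2%) and muscle (28.6%) did not pass, rhombomere (88.2%) and cell cycle (85.7%) lists did, and the midbrain list turned above (55.6%). With peaks overlapped in both replicate lists neural crest (80%), endothelium (7.14%) and cell cycle (78.6%) passed. Against the same CpG class the percentages were those of the main setting by construction, and Hox groups 1 to 4 (83.3%), macrophage (7.14%), late glia (9.09%), liver (0%), muscle (14.3%) and adult organ lists (0%) did not pass, which left 6 lists called instead of 12. Without replicate 1 or 2 the ranges were 83.3% to 83.3% for Hox groups 1 to 4, 76.5% to 82.4% for rhombomere, 44.4% to 55.6% for midbrain, 14.3% to 35.7% for endothelium, 21.4% to 28.6% for muscle and 85.7% to 85.7% for cell cycle genes.

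For distal windows, values are percentiles. With 50 kb roof plate (98.5) and neural crest (99.2) lists were outside the limits, and midbrain (38.3), erythroid (15.8), liver (25.7) and cell cycle (28.5) turned below the middle. At a −log10 q of at least 5 erythroid (39.4) and cell cycle (41.4) turned below it and housekeeping (95.3) was no longer outside. With peaks overlapped in both replicate lists neural crest was outside (97.7). Without replicate 1 or 2 the ranges were 95.5 to 99.0 for roof plate and 84.3 to 99.0 for housekeeping genes. For domains, a gap of 5 kb gave a largest domain of 51.3 kb, which was HoxB, as a smaller gap joins fewer regions. Without replicate 1 or 2 there were 20865 to 26102 domains, and 6 to 9 of the largest 10 were found again.

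For motifs, values are odds ratios. In windows of 200 bp RFX turned below 1 (0.969), MEF2 (1.59) and ETS (2.13) did not pass, and NFI, found in no window, gave no value. At a −log10 q of at least 5 NFI turned above 1 (1.80), ETS (1.59) did not pass, and the nuclear receptor word, found in 1 window, gave no value. With peaks overlapped in both replicate lists NFI (1.53) and TCF/LEF (1.01) turned above 1, and MEF2 (1.35) and ETS (1.75) did not pass. Without repeat-masked bases GATA (0.934) and TEAD (0.948) turned below 1, TCF/LEF (0.916) and nuclear receptor words (0.289) passed, and CTCF (0.977) and MEF2 (1.22) did not. Without replicate 1 or 2 the ranges were 1.283 to 1.448 for NFI, 1.05 to 1.19 for RFX, 1.06 to 1.08 for TEAD, 0.988 to 1.03 for TCF/LEF, 1.30 to 1.42 for ETS and 0.586 to 1.13 for nuclear receptor words.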

Other observations

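The gene families and microRNA lists below were chosen after the results of the fixed gene lists had been seen. Among 22 families taken by symbol, genes of cytosolic ribosomal proteins were marked at 73 of 76 promoters (Fisher's exact test against other genes, adjusted p = 1.5e-19), and the 3 unmarked ones were the paralogues Rpl10l, Rpl39l and Rpl3l. Olfactory receptors were marked at 1 of 1091 promoters (Olfr94, adjusted exact p = 4.36e-309, with 2 marked in each replicate list), keratins at 1 of 49 (Krt10, 7.39e-12, with 3 marked in replicate 1), and cytochrome P450 genes of families 2 and 3 at 2 of 55 (Cyp2r1 and Cyp2u1, 7.39e-12). Potassium channel genes were marked less often than other genes, at 28 of 92 promoters (30.4%, adjusted exact p = 0.00682), with 38 marked in replicate 1 and 29 in replicate 2. The families were not compared within CpG classes.

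Some small families were marked throughout without passing the adjustment. All 5 Zic genes had a promoter region in the replicated list and in both replicate lists (adjusted exact p = 0.0728, exact test), as did all 4 Pou3f genes and all 4 Id genes (0.0984 each). Of the 19 Sox genes 14 were marked (adjusted exact p = 0.0728), and Sox7, Sox8, Sox15, Sox17 and Sox18 were not. Among genes of axon guidance, 7 of 8 ephrins (0.0833), 10 of 14 Eph receptors (0.165), 14 of 20 semaphorins (0.0984), 7 of 9 plexins (0.165) and 5 of 7 Slit and Robo genes (0.344) were marked. Of 19 Wnt ligands 6 were marked (Wnt3, Wnt3a, Wnt4, Wnt5a, Wnt7a and Wnt7b, adjusted exact p = 0.344).

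A hypothesis drawn from the Mir9-1 and Mir9-3 domains and from the strong distal region at Mir124-2hg was that loci of microRNAs of neural tissue may be acetylated more than those of other tissues. Within 20 kb on each side, 12 neural microRNA loci held a mean of 14.3 kb of acetylated sequence (SD 10.8) and 14 loci of other tissues 0.205 kb (SD 0.408), with a permutation p of 2e-05, the smallest that 100000 permutations can give, in which the loci that prompted the hypothesis are included. Mir9-1 had 30.7 kb, Mir9-3 29.2 kb, Mir9-2 24.1 kb and Mir124a-1 15.3 kb, whereas the liver microRNA Mir122 and the muscle microRNA Mir206 had 0 kb. Because the Mir9 and Mir124a loci had prompted the hypothesis, the 6 other neural loci were tested alone, and their mean of 7.61 kb (SD 9.02), led by Mir219a-2 with 24.6 kb, was also above the other loci (two-sided exact permutation p = 0.000774, higher than the other group's mean at 5 of 6 loci, with 0 kb at Mir128-1). Some loci of the muscle group, such as Mir1a-2 and Mir133a-1, share their windows and are not independent, and the choice of microRNAs was made on the same data. Regions at protein-coding promoters were counted as well, and the loci were not matched on gene density. The difference is therefore not shown to belong to the microRNA loci and not to neighbouring genes.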
